A study of Homo sapiens with 63 samples.

How the data were processed

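Gene expression was measured by RNA sequencing in 63 libraries from 3 established human prostate cancer cell lines. DU145 is described in the labels as lacking the androgen receptor, and LAPC4 and VCaP as expressing it. Each line had 7 arms of 3 replicates, which were vehicle (DMSO), R1881, 11KT and 11OHT, and each of these 3 androgens together with enzalutamide. R1881 is a synthetic androgen, 11KT and 11OHT are 11-oxygenated androgens, and enzalutamide is an androgen receptor antagonist. Per the labels, cells were kept for 72 h in 2% charcoal-stripped serum and then exposed for 24 h to 10 nM androgen, with or without 10 µM enzalutamide, at 0.05% DMSO. The labels give an RNA integrity number of at least 9.5, selection of polyadenylated RNA and a directional library kit. There was no arm with enzalutamide alone. The labels do not say whether replicates were separate cultures, so every p-value measures the spread between these samples.

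The deposited count table holds estimated counts per gene (expected counts), which were not whole numbers and were not scaled between libraries. The deposited TPM table holds TPM (transcript abundance scaled by length and depth) by the authors, which sum to 798.7 k to 838.1 k per library, so it holds part of the quantified transcripts. Per the labels, the authors' processing tools were Trimmomatic 0.39, FastQC 0.12.1, MultiQC 1.23, kallisto 0.46.1 and DESeq2 1.42.1 with genome build GRCh38. The annotation release and the counting strand were not stated. The tables hold 19703 genes, of which 352 have no symbol and 725 had no count in any library; 42 symbols are carried by more than 1 gene ID. Gene positions were taken by gene ID from GENCODE release 29 on GRCh38.

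Counts were rounded and tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest with robust estimation), after TMM scaling and filterByExpr by group. Each line was fitted on its own 21 libraries with 1 mean per arm, which left 13532 genes in DU145, 12892 in LAPC4 and 14082 in VCaP. The difference between the R1881 responses of VCaP and LAPC4 was an interaction contrast over the 42 libraries of both lines and 14742 genes. Tests were two-sided, and genes were called past the threshold at a Benjamini-Hochberg adjusted p under 0.05 over the genes of that contrast. In all, 29 contrasts were fitted. Where counts at an unadjusted p under 0.05 are given, chance alone gives a share of 0.05 of the genes tested on average. Log2 fold changes are given with their standard error (SE), taken from the fitted model, with n = 3 libraries per group unless stated. The procedure was tested on simulated data, where edgeR recovered 49.3% of 2-fold changes in LAPC4 and 52.2% in VCaP, with 0 false calls of 92 and 4 of 113. DESeq2 made 19 false calls of 133 and 29 of 158. Each simulation changed 66 or 67 genes at each of 1.5-, 2- and 4-fold, with no length trend and no pairing of replicates. The real R1881 contrast in VCaP had 6361 genes past the threshold, so these shares need not hold there.

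The design, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The named genes were, for every line, the panel AR, NR3C1, KLK3, KLK2, TMPRSS2, FKBP5, NKX3-1, ERG, UGT2B17 and HSD11B2. For each contrast they were also the genes with the largest absolute log2 fold change among those with a symbol and past the threshold. They needed a mean of at least 10 CPM (counts scaled by library total and TMM factor) in the higher group and no overlap between the groups' libraries. Such a gap between 3 and 3 libraries has a 10% share by chance. The rule took 10 genes per direction for R1881 against DMSO in LAPC4 and VCaP and 5 per direction for the other contrasts; for the inhibitor effect in DU145 and the line difference the overlap condition did not apply. The 11KT and 11OHT arms were also read at the genes named for R1881. From each described list, up to 4 members with the largest change past the threshold were taken, or the highest expressed members where none passed. Symbols of small RNAs and clone names were left out.

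The 28 gene lists were written from general knowledge, with 576 symbols of which 572 matched the tables. They cover androgen-induced genes, androgen-repressed genes, DNA replication, mitosis, sterol synthesis, fatty acid synthesis, the secretory and endoplasmic reticulum (ER) stress machinery, glucocorticoid receptor targets, steroid metabolism, PXR targets, AHR and NRF2 targets, polyamine metabolism, the ATF4 amino acid response, hypoxia and glycolysis, interferon response, immediate early genes, heat shock, luminal epithelium, basal epithelium, neuroendocrine genes, mesenchymal genes, fibroblast, leukocyte and endothelial markers, ERG fusion targets, mitochondrially encoded genes, p53 targets and WNT targets. Lists with at least 3 measured members were tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated per list. A list score was the mean log2 CPM of its detected members per library (prior count 1), compared between arms with limma over the 21 libraries of the line, with a 95% interval. The androgen-induced list shares 3 members with the fatty acid list, and the androgen-repressed list shares 5 with steroid metabolism.

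Alternatives were DESeq2 1.42.0, RLE scaling, scaling by total counts, no filter on low counts, replicate number as a block, limma on log2 TPM (pseudocount 1), a fit on the compared libraries alone, and leaving out each library in turn. Gene length offsets, these offsets with the block, and leaving out 5 libraries low in long transcripts were chosen after seeing the data. Replicate numbers were taken to pair libraries where residuals of like-numbered libraries correlated across genes above 0.1 in all 3 pairs of arms. Total counts per library were 20.77 to 30.56 M in DU145, 22.25 to 32.4 M in LAPC4 and 18.9 to 35.44 M in VCaP. Where a group had no count for a gene, the fold was computed against a floor of 3 counts over the group and is a lower bound; such floors and counting intervals cover counting error only. No library was left out of the main tests. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.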

Results

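RNA levels were compared in DU145, LAPC4 and VCaP prostate cancer cells after 24 h with vehicle, R1881, 11KT or 11OHT, each androgen with and without enzalutamide, with 3 libraries per arm and 21 per line. The labels place the study in castration-resistant prostate cancer and ask how the 11-oxygenated androgens act there. Median total counts per library were 25.57 M in DU145, 25.21 M in LAPC4 and 24.65 M in VCaP. AR, the androgen receptor (ENSG00000169083, chromosome X, 67544032 to 67730619 on GRCh38), had 0 counts in every DU145 library, under the floor of 3 counts. In vehicle it stood at 406 ± 105 CPM (counts scaled by library total and TMM factor, mean ± SD, n = 3) in LAPC4 and at 3971 ± 429.8 CPM in VCaP. NR3C1, the glucocorticoid receptor, was at 164.4 CPM in DU145, 21.8 CPM in LAPC4 and 8.43 CPM in VCaP vehicle cells.

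Counts fell off with gene length in 5 of the 63 libraries. Slopes of log2 CPM, relative to each gene's median over the line, were taken per doubling of gene length. Gene length was a relative value, the deposited counts over TPM averaged over these libraries, and not an annotated length. The slope was −0.470 in VCaP 11KT+enzalutamide replicate 1, −0.216 in replicate 2 of that arm and −0.390 in LAPC4 11OHT replicate 3. It was −0.409 in LAPC4 11OHT+enzalutamide replicate 2 and −0.263 in DU145 11KT+enzalutamide replicate 2, against −0.111 to 0.092 in the other libraries. Values from these arms carry this difference.

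**Figure D1:**
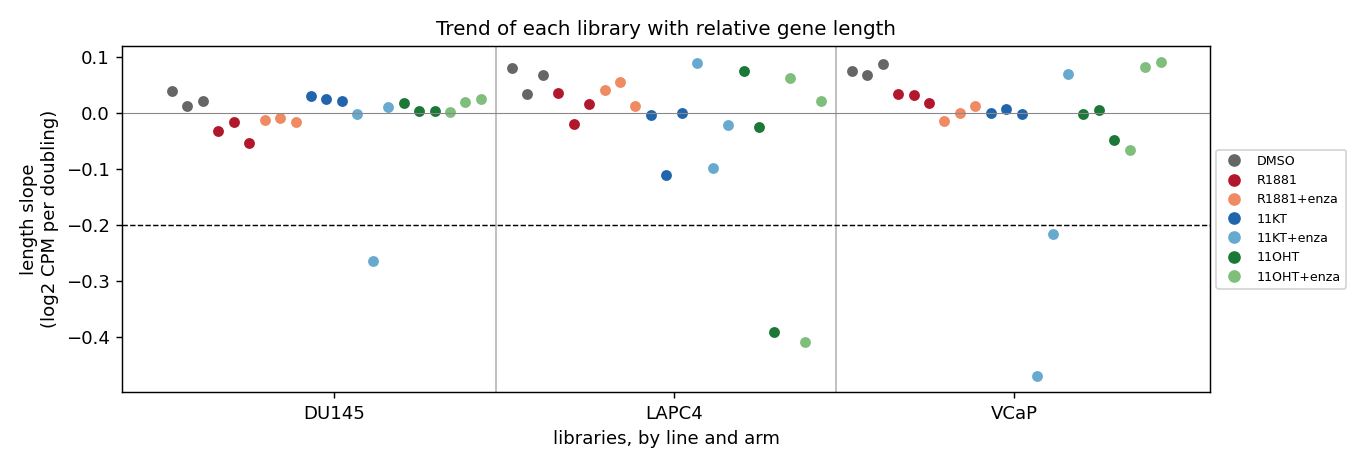
Slope of log2 CPM per doubling of gene length, 1 point per library, by line (sections) and arm (colours), with a dashed line at −0.2. The 5 libraries below it lie at −0.263, −0.390, −0.409, −0.470 and −0.216.

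In VCaP, R1881 raised the known androgen receptor targets by large factors. TMPRSS2, the membrane protease whose promoter drives the ERG fusion of this line (ENSG00000184012, chromosome 21, 41464551 to 41531116), rose from 50.8 ± 5.71 to 1149 ± 36.3 CPM (mean ± SD, n = 3), a log2 fold change of 4.50 ± 0.16 (SE, adjusted p = 1.1e-12). FKBP5, a co-chaperone of steroid receptors (ENSG00000096060, chromosome 6, 35573585 to 35728583), rose by 5.05 ± 0.21 (adjusted p = 5.39e-12). KLK3, which encodes prostate-specific antigen (ENSG00000142515, chromosome 19, 50854915 to 50860764), rose from 19.9 ± 5.31 to 282.6 ± 36.1 CPM, by 3.83 ± 0.27 (adjusted p = 3.08e-09). KLK2 rose by 2.39 ± 0.25, NKX3-1 by 1.29 ± 0.10 and ERG by 2.51 ± 0.13. The largest rises were in PLP1, a myelin protein gene with 0 counts in vehicle and at least 1281-fold more with R1881, and in STEAP4, a metalloreductase gene (9.04 ± 0.37). TBX15 (7.85 ± 0.36), SLC2A3 (6.24 ± 0.52), ADGRG2 (4.64), BHLHA15 (4.46) and SLC15A2 (4.46) followed. ORM2 (6.82) has a near copy, so its value is uncertain.

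The largest falls in VCaP with R1881 included signalling genes. WNT2, a WNT ligand (ENSG00000105989, chromosome 7, 117275451 to 117323289), fell by 7.26 on the log2 scale (SE 0.31, adjusted p = 5.62e-12), and SHH, the sonic hedgehog ligand, changed by −6.19 ± 0.33. MET, the hepatocyte growth factor receptor gene, changed by −6.15 ± 0.72, SLC3A1 by −6.93, LRRTM3 by −6.80, LRRN1 by −5.66, GPR85 by −5.65 and PCDH19 by −5.18. UGT2B15 (−7.96 ± 0.62) and UGT2B17 (−6.04 ± 0.69), which encode enzymes that glucuronidate androgens, fell as well, with uncertain values because close relatives share their reads. AR itself changed by −2.60 ± 0.45 (adjusted p = 0.000118), to 657 ± 87.9 CPM, and NR3C1 by −1.05 ± 0.27. HSD11B2, whose enzyme oxidises 11OHT to 11KT, did not pass the threshold (−0.24, adjusted p = 0.453).

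Of 71 measured genes of the androgen-induced list, 56 rose and 4 fell in VCaP with R1881 (57 and 5 adjusted over the list alone), with a median of 1.66 and adjusted p = 0.00146 with an estimated correlation. ADAM7, a member of this list, changed by −5.36 ± 0.77. Of 29 androgen-repressed genes, 20 fell and 3 rose (22 and 3 adjusted over the list alone; adjusted p = 0.0204 with an estimated correlation). Sterol synthesis genes rose together, 22 of 26 up and 0 down (22 adjusted over the list alone; adjusted p = 0.0276 with an estimated correlation), among them STARD4 (2.77 ± 0.28), INSIG1 (2.64 ± 0.18) and DHCR24 (2.54 ± 0.17). The secretory and ER stress list had 26 of 29 up and 0 down (26 adjusted over the list alone; adjusted p = 0.0176 with an estimated correlation), with SEC24D at 2.76 ± 0.16, DNAJC3 at 2.20 ± 0.12 and SDF2L1 at 2.19 ± 0.23. Among 22 fatty acid synthesis genes 14 rose and 2 fell (14 and 2 adjusted over the list alone), with ACSL3 at 3.32 ± 0.14 and FASN, the fatty acid synthase gene, at 2.45 ± 0.30; the list test gave adjusted p = 0.000361, and adjusted p = 0.236 with an estimated correlation. DNA replication genes fell, 27 of 35 down and 0 up (27 adjusted over the list alone; median −0.85), with CDT1, the replication licensing factor, at −1.61 ± 0.17 and MCM2, a helicase subunit gene, at −1.58 ± 0.17. That list gave adjusted p = 2.05e-07, and adjusted p = 0.246 with an estimated correlation.

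In all, 6361 of 14082 genes passed the threshold in VCaP with R1881, 3039 higher and 3322 lower (2409 and 3779 with total counts), and 1080 and 1707 of these by at least 2-fold. With each of the 6 libraries left out the count lay between 5431 and 5751. Of the 112 named genes past the threshold, 105 stayed past it with each library left out, the genes given values above among them. Scaling by total counts moved the median log2 fold change of all genes from −0.03 to −0.13, so changes in this line are relative to the bulk of genes.

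**Figure D2:**
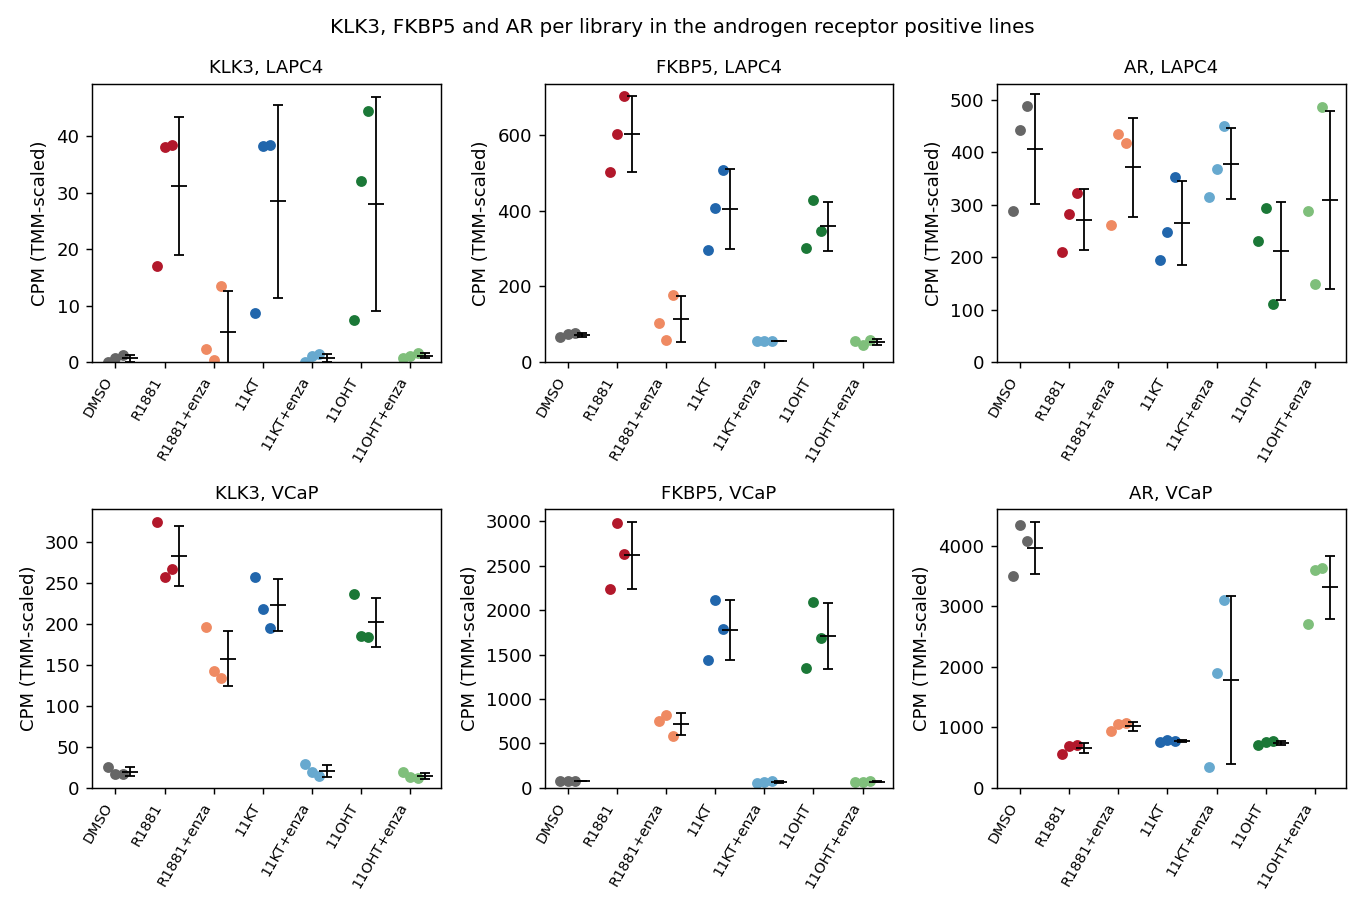
Expression of KLK3, FKBP5 and AR in LAPC4 and VCaP as CPM on a linear axis from 0, by arm, with 1 point per library and bars for the mean and SD of 3 libraries. In VCaP, KLK3 averaged 19.9 CPM with vehicle, 282.6 with R1881, 157.5 with R1881+enzalutamide and 20.8 with 11KT+enzalutamide.

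The 11-oxygenated androgens moved the same target genes in VCaP. With 11KT, TMPRSS2 rose by 4.05, FKBP5 by 4.50 ± 0.21 (adjusted p = 2.67e-11), KLK3 by 3.49, ERG by 2.36, STEAP4 by 8.76, TBX15 by 7.29 and SLC2A3 by 6.19, and PLP1 was at least 777-fold higher. With 11OHT, TMPRSS2 rose by 4.06, FKBP5 by 4.44 ± 0.21 (adjusted p = 2.5e-11), KLK3 by 3.34, ERG by 2.37, STEAP4 by 8.85 and TBX15 by 7.25, and PLP1 was at least 984-fold higher. AR fell with both, at −2.35 ± 0.44 (adjusted p = 0.000351) with 11KT and −2.41 (adjusted p = 0.000285) with 11OHT. WNT2 changed by −6.03 with 11KT and by −6.64 with 11OHT. MET had 1 count over the 3 libraries with 11OHT against 1131 in vehicle, a 1131-fold ratio scaled for depth with a counting interval of 202.5 to 44700.

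Gene groups followed in VCaP. The androgen-induced list had 56 up and 5 down of 71 with either 11KT or 11OHT (57 and 5, and 56 and 5, adjusted over the list alone; adjusted p = 0.000951 and 0.00122 with an estimated correlation). The androgen-repressed list had 22 of 29 down and 3 up with 11KT (22 and 4 adjusted over the list alone) and 20 down and 3 up with 11OHT (21 and 3 adjusted over the list alone); its adjusted p was 0.0148 and 0.0156 with an estimated correlation. Sterol synthesis had 22 of 26 up with each (22 with 11KT and 23 with 11OHT adjusted over the list alone; adjusted p = 0.0148 and 0.0179 with an estimated correlation), with DHCR24 at 2.54 and 2.48. The secretory and ER stress list had 26 of 29 up with 11KT and 25 with 11OHT (26 and 25 adjusted over the list alone; adjusted p = 0.0148 and 0.0156 with an estimated correlation), with SEC24D at 2.54 and 2.37. Of 35 DNA replication genes 16 fell with 11KT and 9 with 11OHT (16 and 7 adjusted over the list alone), with CDT1 at −1.04 and −0.94 and MCM2 at −0.92 and −0.81. The replication list gave adjusted p = 0.00178 and 0.0317, and adjusted p = 0.605 and 0.746 with an estimated correlation.

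The counts in VCaP were 5712 genes with 11KT (2808 higher, 2904 lower; 2238 and 3285 with total counts) and 5631 with 11OHT (2839 higher, 2792 lower; 2271 and 3154 with total counts). R1881 and 11KT shared 2620 higher genes against 606 if independent, and 2625 lower against 685.1, with r = 0.902 between log2 fold changes across genes, which are not independent replicates. R1881 and 11OHT shared 2536 higher and 2506 lower genes (r = 0.892). The 3 vehicle libraries are common to both sides. For the first pair, 5 simulations in which no arm differed from vehicle gave r = 0.485 and a covariance of 0.0738, against 1.127 observed. They also gave 0 shared genes in either direction. With no changed gene, that 0 does not measure the overlap that shared controls add. Part of the excess of shared genes over independence can still come from the shared controls.

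In LAPC4, R1881 raised a smaller number of genes, among them targets shared between steroid receptors. FKBP5 rose from 71.7 to 602.2 ± 100.4 CPM, a log2 fold change of 3.07 ± 0.30 (adjusted p = 0.000122), SGK1, a steroid-induced kinase gene, by 2.55 ± 0.30 (adjusted p = 0.000402) and ZBTB16, a transcription factor gene (ENSG00000109906), by 5.40 ± 0.93 (adjusted p = 0.00419). PGC, the progastricsin gene (ENSG00000096088), rose by 6.27 ± 0.89 (adjusted p = 0.000942), CHRNA2, a nicotinic receptor subunit gene (ENSG00000120903), by 6.65 ± 1.1, KLK2 by 5.78 ± 0.99 (adjusted p = 0.00418), UNC5B by 4.92 ± 0.68, ETNK2 by 4.35 ± 0.49 and ZNF385B by 3.19 ± 0.43. UGT2B11 (7.65 ± 1.1) and NBL1 (5.08 ± 1.20) rose with reads that near copies share. KLK3 rose from 0.658 to 31.2 ± 12.3 CPM, by 5.51 ± 1.20 (adjusted p = 0.0208), and HSD11B2 by 1.11 ± 0.27 (adjusted p = 0.0346). AR (−0.58 ± 0.38, adjusted p = 0.733), TMPRSS2 (0.16 ± 0.10, adjusted p = 0.734) and NKX3-1 (0.52 ± 0.28, adjusted p = 0.577) did not pass the threshold. With replicate as a block NKX3-1 did (0.56, adjusted p = 0.0414), and AR (−0.57, adjusted p = 0.501) and TMPRSS2 (0.16, adjusted p = 0.453) did not.

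Genes that fell in LAPC4 with R1881 included SOX2, a stem cell transcription factor gene (ENSG00000181449), at −3.05 ± 0.47 (adjusted p = 0.0022) and ASCL1, a neural transcription factor gene (ENSG00000139352), at −2.12 ± 0.41 (adjusted p = 0.00817). PCDH19 (−2.14 ± 0.29), TNFSF10, the death ligand TRAIL (−1.66 ± 0.27, adjusted p = 0.00346), IRF1, an interferon-regulated transcription factor gene (−1.62 ± 0.22, adjusted p = 0.000748), ATP13A5 (−1.71), RASSF5 (−1.63) and DENND2B (−1.60) fell too, as did CA10 (−2.60 ± 0.63), TNFSF15 (−2.24), GLYATL2 (−1.86) and FOXQ1 (−1.85). Of 7 measured neuroendocrine genes, SOX2 and ASCL1 fell and 5 did not pass (2 down adjusted over the list alone; adjusted p = 0.0204 with an estimated correlation). Of 68 androgen-induced genes 17 rose and 1 fell (26 and 2 adjusted over the list alone; median 0.60; adjusted p = 0.0204 with an estimated correlation). Of 20 glucocorticoid receptor targets, a list that shares FKBP5 with the androgen-induced list, 7 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.98; adjusted p = 6.89e-06 with an estimated correlation), PER1 by 1.34 ± 0.23. None of 35 DNA replication genes passed singly (0 adjusted over the list alone), and the list lay higher (median 0.18, adjusted p = 5.04e-07, and adjusted p = 0.031 with an estimated correlation). In the androgen-repressed list 3 of 20 rose (UGT2B11, UGT2B28 and KCNMA1) and 0 fell (3 and 1 adjusted over the list alone). Its median was −0.58, its mean 0.20 and its test pointed down (adjusted p = 0.374). With replicate as a block 30 androgen-induced genes rose and 2 fell, 12 glucocorticoid receptor targets and 2 replication genes rose and 0 fell, and 4 androgen-repressed genes rose and 8 fell.

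With 11KT, LAPC4 changes in the same genes were FKBP5 2.49 ± 0.30 (adjusted p = 0.00183), SGK1 2.07 ± 0.29 (adjusted p = 0.00471), CHRNA2 7.00 ± 1.1 (adjusted p = 0.00813), PGC 5.82 ± 0.87, KLK2 5.21 ± 0.97 (adjusted p = 0.0196), ZBTB16 5.11 ± 0.92, SOX2 −2.37 ± 0.44 (adjusted p = 0.0196) and ASCL1 −1.93 ± 0.40 (adjusted p = 0.0357). With 11OHT they were FKBP5 2.32 ± 0.29 (adjusted p = 0.00453), SGK1 1.93 ± 0.29 (adjusted p = 0.00772), CHRNA2 6.92, PGC 5.73, KLK2 5.12 ± 0.97 (adjusted p = 0.0278), ZBTB16 4.69 ± 0.91, IRF1 −1.19 and ASCL1 −2.35. Of the 7 neuroendocrine genes, SOX2 and ASCL1 among them, 2 fell with 11KT and 1 with 11OHT, and 2 with either when replicate was a block. KLK3 missed the threshold with 11KT (5.38 ± 1.20, adjusted p = 0.0523) and with 11OHT (5.36, adjusted p = 0.0549). With replicate as a block it passed with 11KT (5.5, adjusted p = 0.0027) and with 11OHT (5.39, adjusted p = 0.00316), whose replicate numbers did not pair with vehicle. The androgen-induced list had 6 of 68 up and 0 down with 11KT, and 6 up and 1 down with 11OHT (15 and 1, and 18 and 1, adjusted over the list alone; adjusted p = 0.123 and 0.152 with an estimated correlation). Of 20 glucocorticoid receptor targets 4 rose with each (9 and 10 adjusted over the list alone; adjusted p = 5.93e-05 and 0.000177 with an estimated correlation). Among 13 mitochondrially encoded genes 2 fell with 11KT, COX1 by 0.87 on the log2 scale, and 1 with 11OHT (12 and 12 adjusted over the list alone; adjusted p = 0.119 and 0.152 with an estimated correlation). With replicate as a block 21 androgen-induced genes rose and 1 fell with 11KT, 7 glucocorticoid receptor targets rose and 10 mitochondrially encoded genes fell. LAPC4 11OHT replicate 3 is 1 of the libraries low in long transcripts.

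The LAPC4 counts were 277 of 12892 genes with R1881 (146 higher, 131 lower; 130 and 140 with total counts), 77 with 11KT (45 higher, 32 lower) and 71 with 11OHT (42 higher, 29 lower). Like-numbered replicates correlated for R1881 and 11KT against vehicle, and with replicate as a block the counts were 751 and 505; with 11OHT it was 418. Leaving out LAPC4 DMSO replicates 1, 2 and 3 in turn gave 178, 133 and 116 genes for R1881, 5, 1 and 4 for 11KT, and 3, 0 and 0 for 11OHT. It gave 141 and 122 genes for R1881 without R1881 replicates 2 and 3, 11 and 45 for 11KT without 11KT replicates 2 and 3, and 12 and 18 for 11OHT without 11OHT replicates 2 and 3. Without the 5 libraries low in long transcripts, chosen after seeing the data, the counts were 560, 621 and 41. For R1881, 20 of 43 named genes stayed past the threshold with each library left out, FKBP5, SGK1, PGC, KLK2, SOX2, IRF1 and TNFSF10 among them; KLK3 lost its call in 5 of 6 settings (adjusted p up to 0.103) and HSD11B2 in 6 (up to 0.168). For 11KT only FKBP5 of 20 did (up to 0.0307), and for 11OHT 0 of 19 did, FKBP5 failing without DMSO replicates 2 and 3 (up to 0.066).

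The R1881 responses of both receptor-positive lines were compared by an interaction contrast. TMPRSS2 responded more in VCaP, by 4.36 ± 0.18 on the log2 scale (SE, n = 3 per group, adjusted p = 7.07e-18), as did STEAP4 (9.11 ± 0.64) and FKBP5 (2.01 ± 0.35, adjusted p = 5.88e-05). KLK2 had a larger fold change in LAPC4 (−3.35 ± 0.86, adjusted p = 0.00477), but from a low base. It went from 0.347 to 19.9 CPM there and from 194.9 to 1022 CPM in VCaP. HSD11B2 also responded more in LAPC4 (−1.33 ± 0.38, adjusted p = 0.0105), while AR was lowered more in VCaP (−1.99 ± 0.59, adjusted p = 0.0148). The secretory and ER stress list responded more in VCaP for 24 of 29 genes (25 adjusted over the list alone; adjusted p = 0.000227 with an estimated correlation) and sterol synthesis for 17 of 26 (20 adjusted over the list alone; adjusted p = 0.0415 with an estimated correlation), with SEC24D at 2.97 ± 0.23 and INSIG1 at 2.48 ± 0.22. DNA replication genes were lower in VCaP relative to LAPC4 for 27 of 35 (30 adjusted over the list alone; median −1; adjusted p = 0.0415 with an estimated correlation), MCM2 by −1.72 ± 0.20 and CDT1 by −1.71 ± 0.28. The androgen-induced list had 29 of 71 more positive and 7 more negative (31 and 8 adjusted over the list alone; adjusted p = 0.0323 with an estimated correlation).

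In total 2746 of 14742 genes differed between the lines, 1502 more positive and 1244 more negative in VCaP, a balance that turned with RLE scaling (1274 and 1471), total counts (1219 and 1419) and the length offset (1781 and 1825). Among 12276 genes tested in both, 87 of the 143 LAPC4 genes higher with R1881 were higher in VCaP (32.9 if independent) and 19 were lower. Of 114 lower in LAPC4, 57 were lower in VCaP (24.3 if independent) and 25 were higher; the log2 fold changes had r = 0.245 across genes.

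The androgens were compared directly at the matched dose and time. Between 11KT, which carries a ketone at carbon C11, and 11OHT, which carries a hydroxyl there, the androgen-induced score differed by −0.05 (95% interval −0.19 to 0.09) in VCaP and 0.03 (−0.34 to 0.39) in LAPC4. Against R1881 in VCaP, the androgen-induced score was −0.09 (−0.22 to 0.05, adjusted p = 0.696) with 11KT and −0.14 (−0.27 to 0, adjusted p = 0.284) with 11OHT. In LAPC4 these differences were −0.22 (−0.58 to 0.14, adjusted p = 0.666) and −0.20 (−0.56 to 0.16, adjusted p = 0.773). Single genes lay lower without passing the threshold, FKBP5 in VCaP at −0.55 ± 0.18 (adjusted p = 0.491) with 11KT and −0.61 ± 0.18 (adjusted p = 0.217) with 11OHT, and TMPRSS2 at −0.45 ± 0.14 (adjusted p = 0.453) and −0.44 (adjusted p = 0.25). FKBP5 in LAPC4 was at −0.58 ± 0.28 (adjusted p = 1) and −0.75 ± 0.28 (adjusted p = 0.978).

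The DNA replication score set 11OHT apart from R1881 in VCaP. It was higher with 11OHT than with R1881 by 0.51 (95% interval 0.23 to 0.80, adjusted p = 0.0418), and by 0.38 with 11KT (0.10 to 0.67, adjusted p = 0.322). The score gap between 11OHT and 11KT was 0.13 (−0.15 to 0.41). None of the 35 genes passed singly between 11OHT and R1881 (24 higher adjusted over the list alone), and the list test gave adjusted p = 1.99e-21, and adjusted p = 0.0992 with an estimated correlation. Leaving out each of the 6 libraries of R1881 and 11OHT in turn ended the call every time (adjusted p 0.0562 to 0.218), with differences from 0.44 without 11OHT replicate 3 to 0.57 without 11OHT replicate 2, and log2 TPM gave 0.42 (adjusted p = 0.904). Other scores in VCaP, 11OHT minus R1881, were −0.10 (−0.32 to 0.12) for sterol synthesis, −0.18 (−0.33 to −0.03, adjusted p = 0.269) for the secretory and ER stress list and 0.16 (−0.19 to 0.52) for androgen-repressed genes.

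In the main fit, which has no replicate block, edgeR called 0 genes between androgens in either line. In VCaP it called 10 for 11KT and 36 for 11OHT against R1881 with the block, and 4 and 32 with the length offset, chosen after seeing the data. At an unadjusted p under 0.05 there were 815 genes for 11KT against R1881, 1315 for 11OHT against R1881 and 168 for 11OHT against 11KT in VCaP, and DESeq2 called 36, 139 and 1. In LAPC4 the unadjusted counts were 324, 240 and 341, and DESeq2 called 0, 0 and 1. The blocked count of 11KT against R1881, whose replicate numbers paired, was 0. Chance alone gives on average a share of 0.05 of the 14082 genes tested in VCaP and of the 12892 in LAPC4. The unadjusted count of 815 lies near that share, and 168 and each LAPC4 count lie below it. The counts of 0 do not show that the compounds act alike, and the intervals above bound the score differences. Without the 5 libraries low in long transcripts, chosen after seeing the data, edgeR called 89 genes for 11KT and 577 for 11OHT against R1881 in VCaP.

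**Figure D3:**
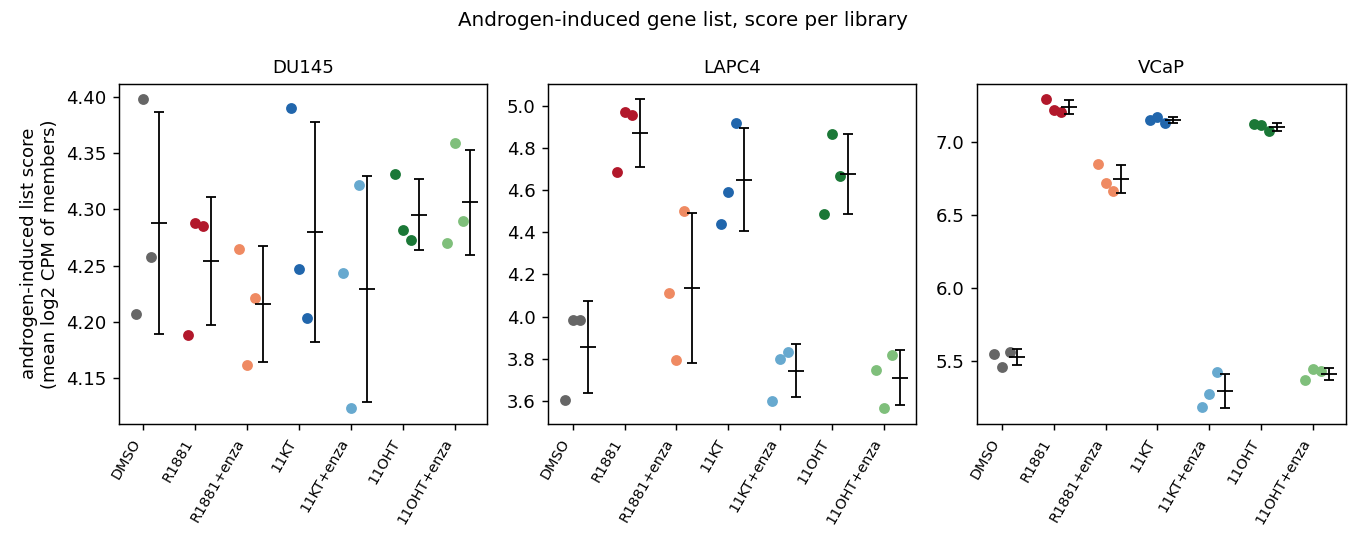
Score of the androgen-induced list (mean log2 CPM of its detected members) per library, by arm and line, with bars for the mean and SD of 3 libraries. In VCaP the R1881+enzalutamide libraries stay above vehicle by 1.22, and the 11OHT+enzalutamide libraries lie at −0.11 from it.

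Enzalutamide lowered the androgen targets in VCaP further with 11KT and 11OHT than with R1881. Added to R1881, it lowered FKBP5 (−1.87 ± 0.18, SE, n = 3 per group, adjusted p = 8.08e-06), TMPRSS2 (−1.11 ± 0.14, adjusted p = 6.23e-05) and KLK3 (−0.84 ± 0.24, adjusted p = 0.0265). KLK2 (−0.26, adjusted p = 0.568), NKX3-1 (−0.18, adjusted p = 0.3), ERG (−0.27, adjusted p = 0.164) and AR (0.63 ± 0.42, adjusted p = 0.402) did not pass. AR stood at 936.6 to 1068 CPM with R1881+enzalutamide and at 555.6 to 714.4 CPM with R1881. Its SE comes from the fit of all 21 libraries, among them 11KT+enzalutamide at 346.1 to 3103 CPM. The missed threshold therefore does not show that AR was unmoved. ADGRG2 (−2.30), PWWP3B (−2.16), PLP1 (−2.13) and ELMO1 (−2.13) fell, and SHH (2.46 ± 0.30), KISS1R (1.93), CDCA7 (1.91), DDN (1.85), FABP5 (1.80) and MYC, the proto-oncogene (1.79 ± 0.20, adjusted p = 2.32e-05), rose. Against vehicle the R1881+enzalutamide arm still had FKBP5 at 3.18 ± 0.19, TMPRSS2 at 3.39 ± 0.15, KLK3 at 2.98 ± 0.26, STEAP4 at 7.84 ± 0.36, PLP1 at least 289.6-fold higher, and AR at −1.96 ± 0.44 (adjusted p = 0.0019).

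Gene groups parted in VCaP when enzalutamide was added to R1881. DNA replication genes rose, 29 of 35 up and 0 down (32 adjusted over the list alone; median 0.92), with UHRF1 at 1.46 ± 0.30, MCM2 at 1.37 ± 0.17 and ORC1 at 1.31 ± 0.29; the list gave adjusted p = 9.98e-24, and adjusted p = 0.0712 with an estimated correlation. Against vehicle this list had 3 up and 0 down of 35 (2 adjusted over the list alone; adjusted p = 0.454), and its score differed by 0.10 (95% interval −0.18 to 0.38). The androgen-induced list had 30 of 71 down and 3 up against R1881 (39 and 3 adjusted over the list alone; adjusted p = 0.00742 with an estimated correlation) and 50 up and 6 down against vehicle (51 and 6 adjusted over the list alone; adjusted p = 0.00249 with an estimated correlation). Sterol synthesis had 3 of 26 down against R1881 (7 adjusted over the list alone; adjusted p = 0.0765) and 22 up against vehicle (22 adjusted over the list alone; adjusted p = 0.0184 with an estimated correlation). The secretory and ER stress list had 10 of 29 down against R1881 (14 adjusted over the list alone; adjusted p = 0.0758 with an estimated correlation) and 22 up against vehicle (25 adjusted over the list alone; adjusted p = 0.0184 with an estimated correlation). The androgen-repressed list had 8 up and 1 down of 29 against R1881 (10 and 1 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation).

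With 11KT and 11OHT the same 10 µM enzalutamide left the androgen-induced score in VCaP at −0.23 (95% interval −0.37 to −0.09, adjusted p = 0.0493) and −0.11 (−0.25 to 0.02, adjusted p = 0.988) from vehicle. The first was −0.14 (adjusted p = 0.213) with the length offset and −0.51 (adjusted p = 0.0242) with log2 TPM. It was −0.10 (−0.27 to 0.06, adjusted p = 0.814) without the libraries low in long transcripts, which leaves replicate 3 alone in this arm, assumed to vary like the other groups. FKBP5 changed by −4.84 against 11KT and −4.58 against 11OHT, TMPRSS2 by −3.97 and −4.01, KLK3 by −3.43 and −3.74, and STEAP4 by −7.87 and −8.51. PLP1 was at least 739.9-fold lower and at least 1157-fold lower. WNT2 rose by 5.88 and 6.39, SLC3A1 by 6.68 and 6.45, and AR by 1.19 ± 0.43 (adjusted p = 0.0281) and 2.15 (adjusted p = 0.000726). Between libraries AR spanned 346.1 to 3103 CPM with 11KT+enzalutamide, where 2 libraries are low in long transcripts, and 2711 to 3627 CPM with 11OHT+enzalutamide. These AR changes therefore do not rank the 2 arms. The androgen-induced list had 61 of 71 down and 4 up against 11KT, and 59 down and 4 up against 11OHT (61 and 5, and 59 and 5, adjusted over the list alone; adjusted p = 0.000695 and 0.000672 with an estimated correlation). Sterol synthesis had 22 of 26 down with each (22 and 23 adjusted over the list alone; adjusted p = 0.0384 and 0.0172 with an estimated correlation), and the secretory and ER stress list 27 of 29 down with each (27 and 27 adjusted over the list alone; adjusted p = 0.0333 and 0.015 with an estimated correlation). DNA replication had 24 of 35 up against 11KT and 11 against 11OHT (24 and 11 adjusted over the list alone), with adjusted p = 9.81e-06 and 0.00839, and adjusted p = 0.391 and 0.697 with an estimated correlation. The androgen-induced score was lower with 11KT+enzalutamide than with R1881+enzalutamide by −1.45 (95% interval −1.59 to −1.32, adjusted p = 4.71e-12) and with 11OHT+enzalutamide by −1.34 (−1.47 to −1.20, adjusted p = 1.75e-11). AR against 11KT kept its call only without 11KT+enzalutamide replicate 1 (adjusted p up to 0.244 without the others), and the score of 11KT+enzalutamide against vehicle lost its call without DMSO replicates 1 or 3 or 11KT+enzalutamide replicates 1 or 2 (adjusted p up to 0.289).

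In VCaP, adding enzalutamide changed 1615 genes against R1881 (905 higher, 710 lower; 974 and 474 with total counts), 6772 against 11KT (3546 higher, 3226 lower) and 5618 against 11OHT (2803 higher, 2815 lower; 3321 and 2154 with total counts). The count against R1881 was 911 without R1881 replicate 2, 1068 without R1881 replicate 3 and 795 without R1881+enzalutamide replicate 3, and KLK3 lost its call in 4 of 6 such settings (adjusted p up to 0.139). Against vehicle, 4729 genes differed with R1881+enzalutamide (2426 higher, 2303 lower; 2070 and 2456 with total counts), and 2068 of the 3039 genes higher with R1881 were also higher there (523.5 if independent). Both sides share the vehicle libraries, and simulated unchanged groups gave a covariance of 0.0795, against 0.909 observed. They gave 0 such genes, which does not measure the overlap from shared libraries because no gene was changed. Part of the excess over independence can come from the shared libraries. With 11OHT+enzalutamide edgeR called 0 genes against vehicle, 269 at an unadjusted p under 0.05, and DESeq2 called 7.

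The 11KT+enzalutamide arm differed from vehicle in 2210 genes (1257 higher, 953 lower; 757 and 942 with total counts) in VCaP, and 2 of its 3 libraries are low in long transcripts. TNKS (−4.22), ATM (−2.06), MYSM1 (−1.78), ATP2B4 (−1.56) and MED13L (−1.56) were lower, and CTSO (2.74), ROMO1 (1.32) and PYCR3 (1.22 ± 0.22) were higher, as were CCDC85B and POP5. Only 2 of the 59 named genes past the threshold stayed past it with each library left out. No panel gene passed, AR standing at −1.16 ± 0.43 (adjusted p = 0.0698). AR spanned 346.1 to 3103 CPM between the 3 libraries of this arm. The count was 414 with a gene length offset, chosen after seeing the data, and 0 in a fit on the compared libraries alone. It was 37, 954 and 85 without DMSO replicates 1, 2 and 3, and 398 and 5513 without 11KT+enzalutamide replicates 2 and 3.

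**Figure D4:**
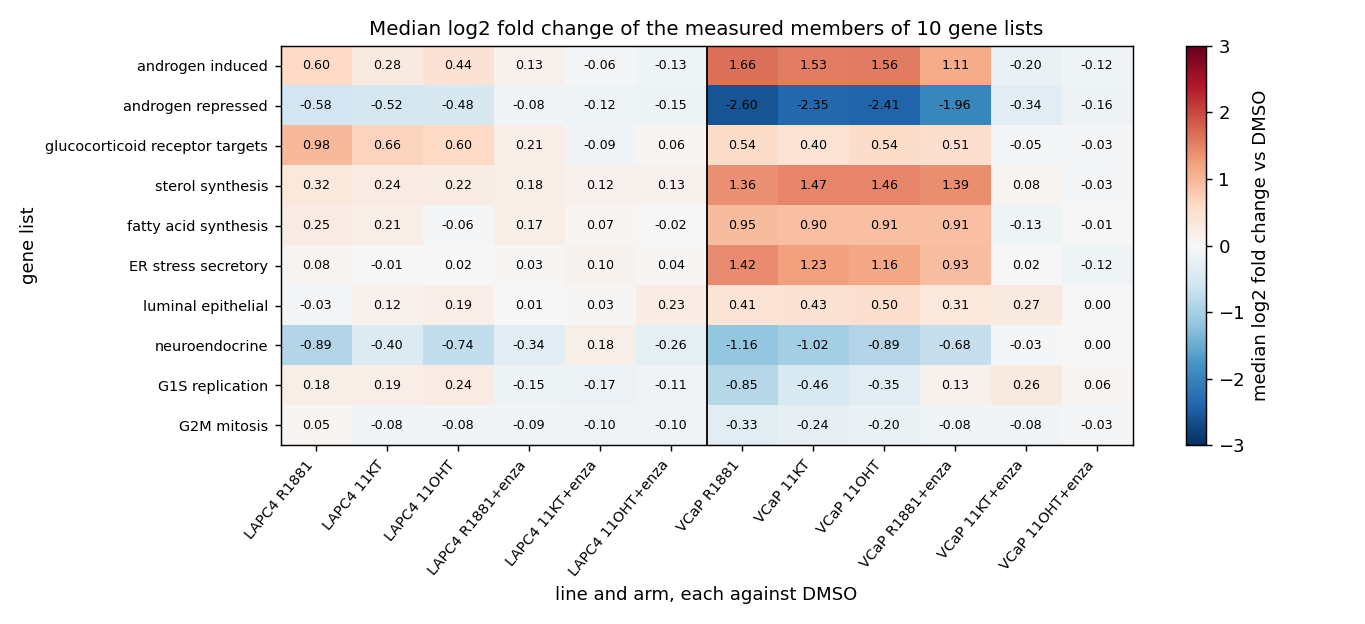
Median log2 fold change against vehicle (colour and number) of the measured members of 10 gene lists (lines of the grid) in 6 arms of LAPC4 and VCaP (columns). In VCaP the DNA replication list stands at −0.85 with R1881 and 0.13 with R1881+enzalutamide, and the sterol synthesis list at 1.36 and 1.39.

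In LAPC4, enzalutamide lowered part of the androgen-raised genes. FKBP5 changed by −2.41 ± 0.29 against R1881 (SE, n = 3 per group, adjusted p = 0.00141), −2.85 ± 0.30 against 11KT (adjusted p = 0.000322) and −2.76 ± 0.30 against 11OHT (adjusted p = 0.000487), and SGK1 by −1.97 ± 0.29, −2.19 ± 0.30 and −2.21 ± 0.30. IRF1 rose by 1.64 ± 0.22, 1.77 ± 0.21 and 1.84. Against 11KT and 11OHT, CHRNA2 changed by −8.47 ± 1.20 and −8.01 ± 1.20, PGC by −5.54 and −5.36, ZBTB16 by −5.66 ± 0.96 and −5.20 ± 0.94, and KLK2 by −4.93 ± 0.95 and −4.58 ± 0.93. Against R1881, ETNK2 (−3.53 ± 0.46), UNC5B (−3.68) and ENPP1 (−2.54) fell and SOX2 (2.39 ± 0.48, adjusted p = 0.0214) and ASCL1 (1.78 ± 0.41, adjusted p = 0.0489) rose. KLK3 (−2.52 ± 1.00, adjusted p = 0.395) and KLK2 (−2.73 ± 0.81, adjusted p = 0.16) did not pass against R1881 (−2.85, adjusted p = 0.0295, and −2.85, adjusted p = 0.0288, with replicate as a block), where KLK3 spanned 0.301 to 13.6 CPM between the R1881+enzalutamide libraries.

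The androgen-induced list in LAPC4 had 3 of 68 down against R1881, 8 against 11KT and 10 against 11OHT, with 1 up in each (15, 21 and 22 down adjusted over the list alone; adjusted p = 0.0362, 0.0626 and 0.0193 with an estimated correlation). Of 20 glucocorticoid receptor targets 5, 5 and 6 fell (9, 10 and 9 adjusted over the list alone; adjusted p = 8.87e-05, 5.22e-05 and 0.000146 with an estimated correlation). DNA replication genes lay lower, with 0, 7 and 4 of 35 down (21, 18 and 17 adjusted over the list alone; adjusted p = 0.00072, 0.000567 and 0.00057 with an estimated correlation). With replicate as a block the numbers down against R1881 and 11KT were 17 and 23 for the androgen-induced list, 8 and 9 for glucocorticoid receptor targets and 10 and 13 for DNA replication. Hypoxia and glycolysis genes, 0 of 22 past the threshold without the block, had 12 and 13 down and 0 up with it. Mitochondrially encoded genes had 10 of 13 up against 11KT with the block (1 without) and 0 against R1881. MCM2 was at −0.57 ± 0.096 (adjusted p = 0.00865) against 11KT and −0.44 ± 0.096 (adjusted p = 0.0319) against 11OHT. Against vehicle the androgen-induced score was 0.28 (95% interval −0.08 to 0.64) with R1881+enzalutamide, −0.11 (−0.47 to 0.25) with 11KT+enzalutamide and −0.15 (−0.51 to 0.21) with 11OHT+enzalutamide.

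In LAPC4, adding enzalutamide changed 104 genes against R1881 (56 higher, 48 lower), 138 against 11KT (57 higher, 81 lower) and 122 against 11OHT (48 higher, 74 lower); with replicate as a block the counts were 592, 649 and 598. Without R1881 replicates 1, 2 and 3 the first count was 58, 29 and 22, and without R1881+enzalutamide replicates 1 and 2 it was 54 and 21. The second was 40 and 62 without 11KT replicates 2 and 3, and 31, 39 and 9 without 11KT+enzalutamide replicates 1, 2 and 3. The third was 79 and 34 without 11OHT replicates 1 and 2, and 48 and 39 without 11OHT+enzalutamide replicates 1 and 3; 11OHT replicate 3 and 11OHT+enzalutamide replicate 2 are low in long transcripts. FKBP5, SGK1 and IRF1 stayed past the threshold with each library left out in all 3 contrasts. Of the named genes past the threshold, 5 of 22 against R1881, 4 of 29 against 11KT and 9 of 24 against 11OHT did so. The remaining named genes lost their call in at least 1 such setting. Of the 45 genes higher with 11KT, 39 fell with enzalutamide, and of the 146 higher with R1881, 45 did (0.283 and 0.544 if independent). These contrasts share the androgen libraries with opposite sign. Simulated unchanged groups gave 0 and 0, which does not measure what the shared libraries add because no gene was changed. In contrasts with no shared library, the 45 genes had a median of −1.11 for enzalutamide added to R1881 and −1.36 for enzalutamide added to 11OHT. The 146 genes had −0.90 for enzalutamide added to 11KT and −0.90 for 11OHT, and 100% of both sets lay below 0 in each. Against vehicle edgeR called 0 genes in each of the 3 arms, 171, 231 and 727 at an unadjusted p under 0.05, and DESeq2 called 1, 1 and 4. The blocked counts were 0, 0 and 3. Without passing, KLK2 and KLK3 stood at 3.05 and 3 against vehicle with R1881+enzalutamide, where KLK3 spanned 0.301 to 13.6 CPM. They stood at 0.28 and 0.25 with 11KT+enzalutamide and at 0.54 and 0.79 with 11OHT+enzalutamide. A count of 0 therefore does not show a return to vehicle. Without R1881+enzalutamide replicate 2 the R1881+enzalutamide count against vehicle was 4.

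In DU145 no panel gene or member of the androgen-induced list passed the threshold with any androgen. FKBP5 was at −0.05 ± 0.10 with R1881 (SE, n = 3 per group, adjusted p = 0.951), 0.05 ± 0.10 with 11KT (adjusted p = 1) and 0.04 ± 0.10 with 11OHT (adjusted p = 1), and KLK3 had 0 counts in every library. Of 58 measured androgen-induced genes 0 rose and 0 fell with each androgen (0 adjusted over the list alone), and the score differed from vehicle by −0.03 (95% interval −0.17 to 0.10), −0.01 (−0.15 to 0.13) and 0.01 (−0.13 to 0.15). Mitochondrially encoded genes lay lower with medians of −0.63, −0.43 and −0.80, with 0 of 13 past the threshold in each (0, 0 and 11 adjusted over the list alone; adjusted p = 0.975, 0.66 and 0.203 with an estimated correlation). COX1 was at −0.63 ± 0.25, −0.41 ± 0.25 and −0.76 ± 0.25. In edgeR 0 genes passed for each androgen, 906, 245 and 269 at an unadjusted p under 0.05, and DESeq2 called 0, 0 and 0; without R1881 replicates 1 and 3 edgeR called 1 and 5 for R1881.

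Enzalutamide in DU145, read as the 9 androgen+enzalutamide libraries against the 9 androgen libraries, raised 4 genes and lowered 0. DHRS3, a retinaldehyde reductase gene (ENSG00000162496, chromosome 1, 12567910 to 12617731), rose by 0.67 ± 0.068 (SE, adjusted p = 7.29e-05), NPC2, a lysosomal cholesterol carrier gene, by 0.32 ± 0.045 (adjusted p = 0.0072), KRT7, a keratin gene, by 0.33 ± 0.057 (adjusted p = 0.0345) and CBS, the cystathionine beta-synthase gene, by 0.24 ± 0.038 (adjusted p = 0.0149). The basal epithelium list lay lower, with 0 of 6 past the threshold (2 down adjusted over the list alone; adjusted p = 0.0221 with an estimated correlation). Its score changed by −0.59 (95% interval −0.86 to −0.33) with enzalutamide added to 11KT, −0.24 (−0.51 to 0.02) to 11OHT and −0.05 (−0.31 to 0.22) to R1881. The highest expressed members were LAMB3 (−0.06 ± 0.036) and DST (−0.21 ± 0.19). The ATF4 list lay higher with 0 of 21 past the threshold (4 adjusted over the list alone; adjusted p = 0.369 with an estimated correlation). DHRS3 and NPC2 stayed past the threshold with each library left out, while KRT7 lost its call in 13 of 18 settings and CBS in 3. The count was 2 without R1881+enzalutamide replicate 3, 11KT replicate 2 or 11OHT+enzalutamide replicate 3; DU145 11KT+enzalutamide replicate 2, low in long transcripts, is among the 9.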

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

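The tests of explanations for patterns 1 to 3 were chosen after the results were seen, except that of the effect spread between LAPC4 and VCaP, as were the gene length offset and the fit without the libraries low in long transcripts; the tests between the lines, the other splits and the other alternatives were planned.

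The interaction test found that the R1881 response differed between VCaP and LAPC4 (VCaP minus LAPC4, log2) for STEAP4 (9.11), ELMO1 (7.19), TMPRSS2 (4.36), FKBP5 (2.01), KLK2 (−3.35), AR (−1.99) and HSD11B2 (−1.33). STEAP4 changed by 9.04 in VCaP and by −0.05 in LAPC4, where it averaged only 0.377 CPM with vehicle and 0.365 CPM with R1881. KLK2 in LAPC4 started from 0.347 CPM with vehicle, against 194.9 CPM in VCaP. ELMO1 changed by 3.68 in VCaP and averaged 0.362 CPM with vehicle and 0.0276 CPM with R1881 in LAPC4, under the floor, so no fold is given there and the fitted difference is no measure of size. TBX15 (7.80), SLC2A3 (6.55), DDC (−7.91), SLC3A1 (−7.00) and INSM2 (−6.79) also differed, but each averaged at most 0.142 CPM in LAPC4 with vehicle or R1881, so no fold is given for that line. UTP14C (−10.01) and DUSP8 (−6.46) had 0 CPM in VCaP with R1881, so these fitted differences are no measure of size. TUBA3D (5.96) and UTP14C have near copies that share reads, so both values are uncertain. Without LAPC4 DMSO replicate 1 the calls of TBX15 (5.93, adjusted p = 1) and SLC2A3 (3.00, adjusted p = 0.97) were lost, and without LAPC4 R1881 replicate 2 that of INSM2 (−3.56, adjusted p = 1). DUSP8 lost its call without VCaP DMSO replicate 3 (−0.40, adjusted p = 1) or any VCaP R1881 library (adjusted p up to 0.0724), and UTP14C without LAPC4 DMSO replicates 2 or 3, VCaP DMSO replicate 1 or any VCaP R1881 library (adjusted p up to 0.0805).

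The same test differed for 7 gene lists, with median differences of 0.79 for androgen-induced genes, −2.72 for androgen-repressed genes, −1 for DNA replication, 1.1 for sterol synthesis, 1.31 for the secretory and ER stress list, 0.52 for luminal epithelium and −0.08 for p53 targets. With an estimated correlation adjusted p was 0.0323, 0.000113, 0.0415, 0.0415, 0.000227, 0.0472 and 0.0415, in that order. The p53 list has a mean of −0.72 and moved in both directions, with 2 genes more positive and 7 more negative in VCaP, BBC3 (−3.34) and PLK2 (−2.34) among the latter.

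Pattern 1 is the set of 2210 genes by which VCaP 11KT+enzalutamide differed from vehicle. Androgen activity left under enzalutamide would raise the androgen-induced score, but it lay at −0.23 (95% interval −0.37 to −0.09) from vehicle, −0.14 (−0.24 to −0.03) with the length offset and −0.51 (−0.84 to −0.18) with log2 TPM, which argues against it; without the libraries low in long transcripts, replicate 3 alone gave −0.10 (−0.27 to 0.06), whose interval includes 0. RNA of another line is argued against by transcripts of the other lines, at 0.0667% of their level there. Loss of long transcripts in single libraries is consistent with the fold changes of these genes, which fell with gene length across the 2210 genes (r = −0.679), with their median shift in the direction of the change of 0.86 and 0.66 in replicates 1 and 2 against 0.18 in replicate 3, and with a count of 414 under the length offset. A response to enzalutamide itself, alike in both arms, is argued against as the whole cause by the 11OHT+enzalutamide arm, where 0 genes passed (269 at an unadjusted p under 0.05, 7 with DESeq2). The 2210 genes had a median of 0.13 there in the direction of their change (interquartile range 0.08 to 0.19), against 0.59 (0.46 to 0.76) with 11KT+enzalutamide. They were chosen in the 11KT+enzalutamide contrast, which raises its own median, and both arms share the vehicle libraries, so these medians alone cannot decide. A response to 11KT and enzalutamide together stays open and untested.

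Pattern 2 is that VCaP R1881+enzalutamide stayed far from vehicle. A missing inhibitor is argued against, because the androgen-induced score fell against R1881 (−0.49, 95% interval −0.63 to −0.36). R1881 RNA mixed into these libraries would leave the same share of every response, but the median share left was 53.61% for androgen-induced genes and −1.938% for DNA replication genes, 55.55 points apart, with interquartile ranges of 39.56 to 76.39 and −31.1 to 17.03. A weaker block of R1881 than of 11KT by the same dose may account for it; in LAPC4 the score of 11KT+enzalutamide minus R1881+enzalutamide was −0.39 (−0.75 to −0.03), −0.39 (−0.68 to −0.10) with replicate as a block, but −0.25 (−0.58 to 0.08) with log2 TPM, and the interval reached 0 without R1881+enzalutamide replicate 1 (−0.41, −0.82 to 0.01) or 3 (−0.21, −0.56 to 0.14) and without 11KT+enzalutamide replicate 1 (−0.32, −0.73 to 0.09) or 2 (−0.42, −0.84 to 0). That explanation stays open, since the interval depends on 4 of the 6 libraries and the design has 1 dose.

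Pattern 3 is the smaller number of genes past the threshold in LAPC4 (277) than in VCaP (6361) with R1881. Sequencing depth is argued against by the ratio of median totals, LAPC4 over VCaP, of 1.023. Wider replicate spread alone is argued against by the spread of true log2 fold changes, estimated at 0.714 in VCaP and 0.279 in LAPC4, a ratio of 2.559 over 9551 genes. A biological difference between the lines, such as the amount of AR, stays open as a hypothesis and was not tested.

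For each comparison of 3 with 3 libraries, 10 splits are too few for a share under 0.05. In LAPC4 the real counts of 277, 77, 71, 104 and 138 genes were reached in 1 of the 10 splits and the highest other split gave 0. For 11OHT+enzalutamide against 11OHT the real count of 122 was reached in 3 splits, the others giving 3223 and 1427; both put 11OHT replicate 3 and 11OHT+enzalutamide replicate 2, low in long transcripts, on the same side, which points to a structure of the samples, though 2 more splits that do so gave 2 and 0. In VCaP the counts of 6361, 5712, 5631, 1615, 6772, 5618 and 4729 genes were each reached in 1 split, with 0 as the highest other, and the count of 2210 in 1, with 1046 as the highest other. Comparisons with 0 genes were matched by all 10 splits, which is fixed in advance for a count of 0 and says nothing about them. Their highest other split gave 0 or 1.

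For the inhibitor effect in DU145, 100 splits of the libraries were drawn, and the real split alone reached 4 genes, the highest other giving 1. This makes chance less likely for that count, but so few genes and 100 splits cannot exclude it. For the line difference, 6 of 100 splits reached 2746 genes, the highest other giving 3403; the 5 others all kept the real division of the VCaP libraries, and the highest split that did not gave 97 genes. Splits that keep that division keep the VCaP response itself, so this count of splits cannot decide on chance.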

How the results depend on the processing

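The alternatives named here were planned, except the gene length offset, the offset with the replicate block and the fit without the 5 libraries low in long transcripts, which were chosen after seeing the data; unless stated, the cause was not tested. RLE scaling left every count within 1.5 times. Of the values of named genes, 986 of 988 kept their call with DESeq2, 987 of 990 with the replicate block, 983 with RLE, 940 with total counts, 932 without the filter, 922 with the length offset, 935 with the offset and block, 890 without the 5 libraries, 802 with log2 TPM, 805 of 971 with the compared libraries alone and 5387 of 6510 with a library left out. Of 177 list calls, 177 were kept with the replicate block and 54 with an estimated correlation.

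Counts in LAPC4 for R1881, 11KT and 11OHT against vehicle, and for enzalutamide added to each, became 466, 359, 283, 295, 387 and 332 with DESeq2; 751, 505, 418, 592, 649 and 598 with the replicate block; 431, 187, 122, 245, 325 and 288 with the length offset; 1303, 1153, 722, 1136, 1311 and 1322 with offset and block; and 691, 51, 4, 67, 39 and 2 with the compared libraries alone, where fewer libraries give the spread. Without the 5 libraries the first 5 became 560, 621, 41, 326 and 461. The 11OHT count was 42 with no filter, and log2 TPM gave 183 for R1881, 31 for 11OHT and 78 for enzalutamide added to 11OHT. The arms with enzalutamide against vehicle became 1, 1 and 4 with DESeq2, 1, 1 and 4 with offset and block, and 3 for 11OHT+enzalutamide with the block. 11OHT against 11KT became 1 with DESeq2, and 11OHT against R1881 3 with offset and block.

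In VCaP, R1881+enzalutamide against R1881 became 2912 with offset and block, 3648 with the compared libraries alone, 3609 without the 5 libraries and 589 with log2 TPM, and 11KT+enzalutamide against 11KT 2883 with the compared libraries alone. 11KT+enzalutamide against vehicle became 414 with the offset, 868 with offset and block, 0 with the compared libraries alone and 7 without the 5 libraries, where the arm holds replicate 3 alone, assumed to vary like the other groups. 11OHT+enzalutamide against vehicle became 7 with DESeq2, 2 with offset and block, 7 without the 5 libraries and 2 with total counts. 11KT against R1881 became 36 with DESeq2, 10 with the block, 4 with the offset, 52 with offset and block, 47 with the compared libraries and 89 without the 5 libraries; 11OHT against R1881 became 139, 36, 32, 178, 300 and 577, and 1 with total counts. 11OHT against 11KT became 1 with DESeq2. The line difference became 4754 with offset and block, 4802 with the compared libraries and 4384 without the 5 libraries. The inhibitor effect in DU145 became 14 with DESeq2, 12 with the block, 9 with the offset, 35 with offset and block and 2 with the compared libraries.

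With 1 library left out, which leaves 2 in its arm, counts ranged in LAPC4 from 116 to 205 for R1881, 1 to 75 for 11KT, 0 to 86 for 11OHT, 21 to 98, 9 to 93 and 34 to 121 for enzalutamide added to each, and 0 to 4 for R1881+enzalutamide against vehicle. In VCaP they ranged from 5431 to 5751, 4624 to 5041 and 4552 to 5059 for the androgens, 795 to 1279, 5624 to 7847 and 4539 to 4967 for added enzalutamide, 3713 to 4005 and 37 to 5513 for R1881+enzalutamide and 11KT+enzalutamide against vehicle, and 0 to 1 for each pair of androgens. They ranged from 0 to 5 for R1881 and 2 to 6 for the inhibitor effect in DU145, from 2261 to 2543 for the line difference, and stayed at 0 for the others.

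Directions turned with log2 TPM for TCF7 (11OHT against vehicle, −0.01), NR3C1 (11KT+enzalutamide against 11KT, −0.03), LDHA (−0.17) and NR4A1 (−0.12) in 11KT+enzalutamide against vehicle, all in VCaP, and for HPGD (0.13) and NCALD (−0.44) in the line difference. Without the 5 libraries, on 11KT+enzalutamide replicate 3 alone, they turned for HSPE1 (−0.20, 11KT+enzalutamide against 11KT) and, against vehicle in that arm, for DBI (0), PMVK (−0.02), SDF2L1 (−0.20), HSD17B10 (−0.04), CEBPB (−0.05) and CLDN4 (−0.03). Of 40 results of the androgen-induced score, 40 kept their call with the block, 39 with the offset, 39 without the 5 libraries and 38 with log2 TPM, where the androgen-induced score in LAPC4 gave 0.40 (adjusted p = 0.135) for 11OHT against vehicle and −0.49 (adjusted p = 0.0523) for R1881+enzalutamide against R1881; with a library left out 246 of 252 did. The DNA replication score of 11OHT against R1881 in VCaP, outside that tally, lost its call with each of the 6 libraries left out (adjusted p 0.0562 to 0.218) and with log2 TPM (0.42, adjusted p = 0.904). The balance of higher and lower genes also turned with total counts for R1881 against vehicle in LAPC4 (130 and 140). In VCaP it did so for 11OHT (2271 and 3154), R1881+enzalutamide (2070 and 2456) and 11KT+enzalutamide (757 and 942) against vehicle, and for 11OHT+enzalutamide against 11OHT (3321 and 2154). It turned with the length offset for R1881+enzalutamide against R1881 in LAPC4 (118 and 127), and for R1881 (3600 and 3526), 11KT (3269 and 3166) and 11KT+enzalutamide against 11KT (3515 and 3573) in VCaP, and with RLE for 11OHT+enzalutamide against 11OHT (2821 and 2800). At 2-fold, tests on simulated data with 67 such genes per line recovered 82.1% of them in DU145, 49.3% in LAPC4 and 52.2% in VCaP. These shares need not hold where far more genes change.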

Other observations

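The test of the replication hypothesis in the last paragraph of this part was chosen after the result was seen; the lists were fixed beforehand.

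In VCaP with R1881, luminal epithelial genes had 8 of 14 up and 1 down (9 and 1 adjusted over the list alone; adjusted p = 0.0774 with an estimated correlation), with AGR2 at 3.36 ± 0.37 (log2, SE, n = 3 per group), SPDEF at 2.71 ± 0.13 and KRT8 at 1.64 ± 0.14. Neuroendocrine genes had 8 of 15 down and 2 up (9 and 3 adjusted over the list alone; adjusted p = 0.0774 with an estimated correlation), with NCAM1 at −2.14 ± 0.25, DLL3 at −1.48 ± 0.20 and CHGA at −1.38 ± 0.16. p53 targets had 9 of 20 down and 4 up (10 and 4 adjusted over the list alone; adjusted p = 0.154), with the pro-apoptotic BBC3 at −3.62 ± 0.20, PLK2 at −2.43 ± 0.17 and the cell cycle inhibitor CDKN1A at 1.76 ± 0.13. Polyamine genes had 8 of 14 up and 2 down (8 and 2 adjusted over the list alone; adjusted p = 0.188), with ODC1, the ornithine decarboxylase gene, at 2.55 ± 0.16 and ARG2 at −1.84 ± 0.15. Glucocorticoid receptor targets had 10 of 20 up and 3 down (10 and 3 adjusted over the list alone; adjusted p = 0.169 with an estimated correlation), with ERRFI1 at 3.36 ± 0.12 and SGK1 at 2.41 ± 0.24. Hypoxia and glycolysis genes had 10 of 20 up and 2 down (10 and 2 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation), with ADM at −3.08 ± 0.30 and ANKRD37 at 2.61 ± 0.23.

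The other lists in VCaP with R1881 did not pass their test. Up and down counts were 4 and 7 of 19 for steroid metabolism (4 and 7 adjusted over the list alone; adjusted p = 0.39), 7 and 5 of 14 for AHR and NRF2 targets (8 and 5 adjusted over the list alone; adjusted p = 0.47), 5 and 6 of 21 for the ATF4 list (adjusted p = 0.895), 1 and 3 of 17 for interferon genes (adjusted p = 0.774; IFIT3 −1.87 ± 0.29, ISG15 1.30 ± 0.30) and 2 and 4 of 16 for immediate early genes (adjusted p = 0.838). They were 4 and 2 of 10 for heat shock (adjusted p = 0.415), 2 and 1 of 6 for basal epithelium (adjusted p = 0.939), 3 and 4 of 13 for mesenchymal genes (adjusted p = 0.774), 3 and 2 of 11 for ERG fusion targets (adjusted p = 0.846; ADGRF5 −5.38 ± 0.62), 2 and 6 of 11 for WNT targets (adjusted p = 0.299) and 0 and 4 of 33 for mitosis (0 and 0 adjusted over the list alone; adjusted p = 0.264). Adjusted over the list alone these counts were the same except for AHR and NRF2 targets, mitosis, mesenchymal genes (3 and 5) and ERG fusion targets (4 and 2). Of 7 PXR targets 1 rose (adjusted p = 0.868), with a median of −0.17 and a test that pointed up. Mitochondrially encoded genes had 0 of 13 past the threshold (adjusted p = 0.838). Markers of other cell types had 0 up and 3 down of 5 for fibroblasts (adjusted p = 0.178), 0 of 3 for leukocytes (adjusted p = 0.868) and 1 up of 3 for endothelium (VWF 2.31 ± 0.56; adjusted p = 0.838).

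In LAPC4 with all 3 inhibitor arms against vehicle, where no single gene passed, the ATF4 list lay higher (adjusted p = 0.00229, 0.0164 and 0.0798 with an estimated correlation for R1881, 11KT and 11OHT) and DNA replication lay lower (adjusted p = 0.012, 0.0164 and 0.204 with an estimated correlation). Of 21 ATF4 genes 2, 1 and 4 were higher adjusted over the list alone, and of 35 replication genes 0, 0 and 3 were lower. With R1881 alone in LAPC4, fatty acid synthesis had 4 of 20 up and 0 down (4 adjusted over the list alone; adjusted p = 0.259 with an estimated correlation) and sterol synthesis 1 of 26 up (1 adjusted over the list alone; adjusted p = 0.134 with an estimated correlation).

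DNA replication genes in VCaP went back to the vehicle level when enzalutamide was added to R1881, while androgen-induced genes did not. A candidate explanation is that lowering of replication genes needs a stronger androgen signal than induction of androgen targets. The test was whether these genes stood higher with 11OHT, whose androgen-induced score was close to that of R1881 (−0.14, 95% interval −0.27 to 0), than with R1881. The score was higher by 0.51 (0.23 to 0.80), between 0.44 (0.12 to 0.76) without 11OHT replicate 3 and 0.57 (0.24 to 0.89) without 11OHT replicate 2, and 0.42 (−0.03 to 0.88) with log2 TPM. This is a hypothesis found and tested on the same data, and adjusted p for the score went from 0.0418 to as much as 0.218 without R1881 replicate 2.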
